A study of Mus musculus with 4 samples.

How the data were processed

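The series holds 4 microarray libraries from mDCT cells, an immortalised mouse line of the distal convoluted tubule, the kidney segment in which aldosterone-sensitive sodium transport begins. The cells were transfected with a FLAG-tagged human mineralocorticoid receptor (MR), the nuclear receptor that aldosterone binds. They received spironolactone, an MR antagonist, or ethanol 48 h after transfection, and aldosterone or ethanol 2 h later, for 3 h. Biotin-labelled cRNA was made from 250 ng of total RNA and hybridised to an Affymetrix 3' expression array. The treatments were ethanol, 1 nM aldosterone, 100 nM aldosterone, and 100 nM aldosterone after 5 µM spironolactone, with 1 library each. The last is called spironolactone below. No library received spironolactone alone, so its differences from ethanol or 1 nM aldosterone are not those of the antagonist by itself. Each library was assigned to its treatment from its own label.

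The deposited values are probe set intensities on a linear signal scale, computed with MAS5 per the submitters' processing notes; the version, the scaling target and the detection calls are not given in the sources used here. The trimmed mean signal, leaving out 2% of probe sets at each end, was 499.8 in each library, so the arrays had been scaled to a common level before deposit. No further scaling was applied in the main setting. All 4 value columns belonged to samples of the series, and the number of other sample columns was 0.

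The table held 45101 probe sets, of which 64 were array controls. Gene names came from the platform annotation: 34958 probe sets had 1 gene symbol, 932 had several, 9160 were not listed there, and 34754 of the first kind were matched by Entrez identifier to the RefSeq genes of GRCm38.p6, which changed 0 symbols. Probe sets with several symbols or none were given no gene name. For each gene the probe set with the highest mean log2 signal was used, and 6979 of the genes that entered had more than 1. Of 18194 genes, the 11058 whose mean log2 signal was at or above the median of all probe sets, a signal of 55.9, entered the comparisons. No genome build is named in the files, so no coordinates are given, and the assembly above served only for names and for gene span.

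Differences between libraries are differences of log2 signal, with no pseudocount. Genes at least 2-fold higher or lower were counted in each of the 6 pairs of libraries, and genes that parted 2 libraries from the other 2 by at least 1.5-fold were counted for the 3 possible partings. With 1 library per treatment there is no estimate of replicate error: no p-value, standard error or interval is given, every difference is one between libraries, and the number of arrays limits the precision. Where a gene is set against others of its signal level, the reference is the 501 genes nearest to it in mean signal.

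Named genes were chosen by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest genes past 2-fold for 100 nM aldosterone against ethanol and for spironolactone against 100 nM aldosterone, the 8 highest and 8 lowest for 1 nM aldosterone against ethanol, the 12 and 8 largest gaps of the parting by aldosterone alone, the 4 largest members of each gene list, both corticosteroid receptor genes, and 5 genes recalled from memory of the study's publication, which was not at hand to check them. Clone-like names were counted and not printed. Genes above the 75th percentile of signal, 420, were named by the same ranks without the 2-fold rule; that selection was added after seeing the data.

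The 27 gene lists were also fixed before the data were examined. They cover steroid receptor responsive genes, genes induced by aldosterone in the nephron, genes recalled as named by the study, distal ion transport, steroid receptors and chaperones, immediate early genes, circadian genes, the interferon response, NF-kB and cytokines, matrix and fibrosis, cholesterol synthesis, the unfolded protein and amino acid stress response, the xenobiotic and oxidative response, heat shock, hypoxia and glycolysis, p53 targets, S phase, G2 and mitosis, growth factor and TGF-beta signalling, lipid and insulin handling, housekeeping genes, ribosomal proteins, and markers of proximal tubule, collecting duct and intercalated cells, fibroblasts, endothelium and leukocytes. A list's median log2 difference was placed among the medians of 10000 random lists of its size, matched over 10 bins of mean signal. The percentile describes these libraries, and random lists ignore that members of a pathway vary together. A second measure, the number of members among the highest or lowest 1% of the 501 genes nearest in signal, was added after the medians had been seen and after several filters and size rules had been looked at.

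The correlation of both doses' differences from ethanol was set against 100 simulations of unchanged libraries sharing that ethanol library, with the same noise as below. The procedure was tested on simulated data for 100 nM aldosterone against ethanol, with noise drawn from the pair of libraries with the least spread, 1 nM aldosterone and spironolactone. These were treated differently, so the noise is not replicate error. The number of unchanged genes past 2-fold follows from that choice of noise, so it is no measure of false calls and is not used. The simulated overlap and covariance of both doses carry the same limit and are given only beside the observed values. Of 50 genes at each size, 6% of those with a true 1.5-fold difference passed, 50% at 2-fold, 94% at 3-fold and 100% at 4-fold. Over 40 unchanged lists the mean percentile was 53.2.

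The 7 alternatives fixed in advance were quantile normalization, centring each library on its median, no filter, the 75th percentile filter, a pseudocount of 15.0 (the 25th percentile of all values), the median over a gene's probe sets, and a 1.5-fold rule. Added after seeing the data were the 1.5-fold rule above the 75th percentile, the steroid and nephron lists without the recalled genes, signals under the filter raised to it, the median difference over a gene's probe sets at or above the filter, correlations under both filters for all partings, a count of genes at which 1 library stood apart, and the rank correlation of each difference with gene span. The work used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.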

Results

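Gene expression was measured on 1 array for each of 4 treatments of MR-expressing mDCT cells: ethanol, 1 nM aldosterone, 100 nM aldosterone, and 100 nM aldosterone after 5 µM spironolactone. There were no replicates, so no difference could be set against the spread between replicates. The median signal was 58.9 in ethanol, 61.7 with 1 nM aldosterone, 59.5 with 100 nM and 59.7 with spironolactone, and the upper quartiles lay between 419 and 426. Across the 11058 genes that entered, the lowest Pearson correlation between libraries was 0.991 and the highest 0.992. The mouse MR gene, Nr3c2, had signals of 2.35, 21.8, 4.44 and 15.1 in the order above and did not pass the filter; a mouse probe set does not check the human receptor. Nr3c1, the glucocorticoid receptor gene, had signals of 1959, 1998, 1708 and 1871.

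The comparison of 100 nM aldosterone with ethanol asks which transcripts differ after 3 h of the higher hormone dose. Sgk1, the serum- and glucocorticoid-regulated kinase that raises sodium channel activity in the distal nephron, was 2.26-fold higher, with a signal of 1810 against 801. Per1, a circadian repressor induced by corticosteroids, was 2.28-fold higher (527 against 231), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper GILZ, had a signal of 1365 against 711, a log2 difference of 0.94. The steroid-induced co-chaperone Fkbp5 was higher by 0.40 on the log2 scale (0.72 in a second probe set) and the transcription factor Klf9 by 0.45. Tns1, a focal adhesion protein, was higher by 0.70 (0.20 and 0.50 in its other probe sets) and the small GTPase Rasl12 by 0.67.

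The median difference of the steroid receptor responsive list was 0.04 over 23 entered members, the 92.6th percentile among random lists. Of its members 17 were higher than in ethanol, 3 by at least 1.5-fold (Per1, Sgk1 and Tsc22d3), and 0 were lower by that much. Without Sgk1, Tsc22d3 and Fkbp5, which are on a list recalled from memory of the study's publication and not checked against it, the median was 0.03 and the percentile 84.8. On the measure added after seeing the data, 5 members (Sgk1, Tsc22d3, Fkbp5, Per1 and Klf9) lay among the highest 1% at their signal level and 0 among the lowest, where 0.23 were expected at each end; 1 of 10000 random lists held as many. Without the 3 recalled genes 2 members remained there, as many as in 203 of 10000 random lists. The genes induced by aldosterone in the nephron, 4 of whose 13 entered members are also on the steroid list, had a median of 0.24, the 100th percentile; 3 of them are the recalled genes, and without these the median was 0.12 (percentile 96.8), with Per1 alone among the highest 1%. Usp2, a deubiquitinase, went the other way among them, with a difference of -0.59. The 5 genes recalled as named by the study had a median of 0.70, the 100th percentile, which is not independent evidence, since the study drew on these libraries.

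**Figure D1:**
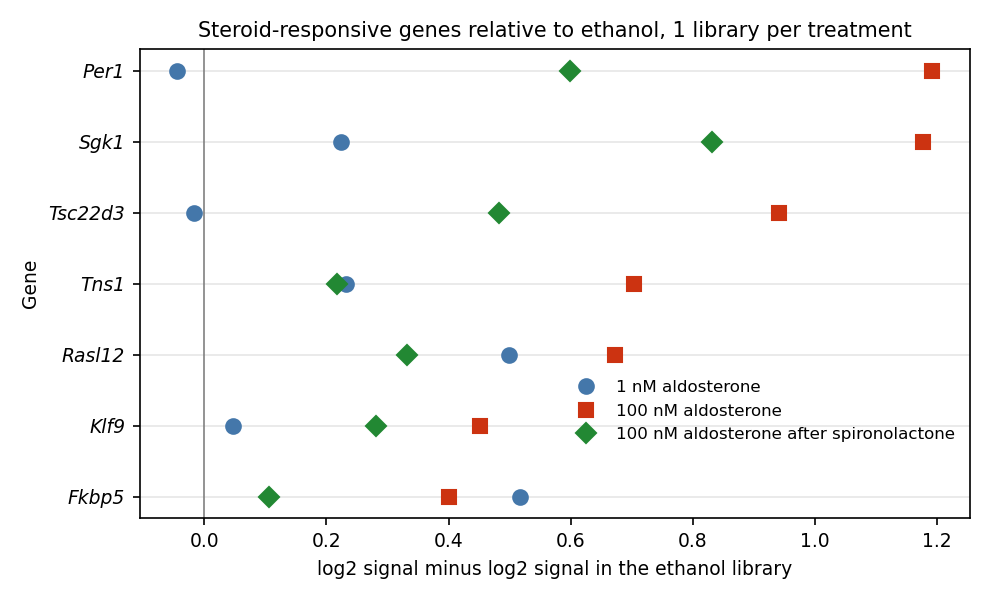
The log2 signal of 7 genes relative to the ethanol library (x axis) is plotted for each gene (y axis), with 1 point per treated library. Of these, 5 are the steroid list members among the highest 1% with 100 nM aldosterone, while 20 of its 23 entered members stayed within 1.5-fold. Tns1 and Rasl12 are only on the list recalled as named by the study. With 100 nM aldosterone Per1 lies at 1.19 and Sgk1 at 1.18; after spironolactone they lie at 0.60 and 0.83, and with 1 nM aldosterone at -0.04 and 0.22.

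Immediate early genes, the first transcripts to respond to growth signals, were lower as a group with 100 nM aldosterone: the median over 25 members was -0.15, the 0.01th percentile. Fosl1, an AP-1 subunit, differed by -0.48 and the nuclear receptor Nr4a2 by -0.46, while Klf6 was higher by 0.59 and the dim Egr3 by 1.22. The growth factor and TGF-beta list had a median of -0.11 (percentile 0.54), with differences of -0.51 for Phlda1, -0.41 for the MAP kinase feedback inhibitor Spry2 and -0.41 for the phosphatase Dusp4. Its member Ski was higher by 1.07, though another Ski probe set differed by 0.10. The p53 targets had a median of -0.11 (percentile 0.66), with -0.44 for Sesn2 and -0.44 for Gtse1. Of these targets 1 was higher by at least 1.5-fold and 0 were lower by that much. With the median over a gene's probe sets, the growth factor list moved to the 13.1th percentile and the p53 list to the 43.0th. The median of the differences of Klf6 over its 5 probe sets was 0.03.

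In the lipid and insulin list, Acaca, which encodes the first enzyme of fatty acid synthesis, differed by -0.51, the insulin receptor substrate Irs1 by -0.50 and the transcription factor Foxo3 by -0.38. The list's median was -0.04 (percentile 13.9), and 4 of its 18 members lay among the lowest 1% at their signal level, as many as in 0 of 10000 random lists. Distal ion transport genes had a median of 0.06 (percentile 87.8), with 0.59 for the sodium channel subunit Scnn1a and 0.24 for the sodium pump subunit Atp1b1. Steroid receptors and chaperones had a median of 0.06 (percentile 95.1), with -0.24 for Hsp90aa1. The circadian list lay at 0.02 (percentile 70.6), with Cry1 at -0.50. Matrix and fibrosis genes lay at 0.02 (percentile 71.2); Ccn2, a matrix-associated growth factor, was higher by 0.75. Cholesterol synthesis lay at -0.03 (percentile 20.8), with its last enzyme Dhcr7 higher by 0.63. Interferon genes lay at -0.04 (percentile 25.6), with Rsad2 at -1.29 and Irf7 at 0.89. NF-kB and cytokine genes lay at -0.06 (percentile 14.6), with the chemokine Ccl20 at -0.55, and hypoxia and glycolysis at -0.06 (percentile 3.51), with Adm at -0.49. Of the 27 lists, 2 lay above the 97.5th and 3 below the 2.5th percentile, where 1.35 were expected outside that range. The 2 above were the list recalled from the study and the nephron list. Without the 3 recalled genes the nephron list lay at the 96.8th percentile, within the range. The expectation takes lists as independent of each other and of these libraries, so no excess is read from the counts.

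By size alone, 82 genes were at least 2-fold higher with 100 nM aldosterone and 41 lower. With signals under the filter raised to its signal of 55.9, a step added after seeing the data, the counts were 47 and 22. No detection calls were at hand, so for a gene whose dimmer signal lay under the filter the fold is given as a lower bound, and the order among such genes carries no meaning. Of the genes named by the rule, the synuclein Sncb was 4.05-fold higher (signal 70.0 to 283). Mycn was at least 3.17-fold higher, Tmem52 2.45-fold, Golga7b 2.45-fold, the antiplasmin gene Serpinf2 2.32-fold (signal 15.3 to 130), Pth2 2.29-fold, Hrct1 2.22-fold, the thromboxane receptor Tbxa2r 2.19-fold and the protein kinase A regulatory subunit Prkar1b 2.05-fold. Snx29, Mybpc3 and the urate transporter Slc22a12 stayed under 2-fold on that bound. The next brightest probe set of Mycn differed by -0.28 and that of Prkar1b by 0.79. Lower were the interleukin receptor kinase Irak1 (2.84-fold, signal 439 against 1246) and Grip2 (2.80-fold), and by at least 3.88-fold the splicing helicase Dhx38, 2.89-fold Fcgr2b, 2.63-fold Slco2b1 and 2.41-fold the mucin Muc20 (signal 10.4 against 135). Mir142, the plexin Plxna4, Carns1, Klf14, Hes7 and Mapk15 stayed under 2-fold on that bound. By the signals as deposited, with no lower bound, at 9 of the 12 higher genes the ethanol library was 2-fold below all 3 others, and 10 were also 2-fold higher than ethanol with spironolactone. At 9 of the 12 lower genes, among them Muc20, Mir142, Fcgr2b and Irak1, the 100 nM library was 2-fold below all 3 others. These counts were added after seeing the data. Picking genes by their difference from a library favours genes at which that library stands apart. Such counts, here and below, therefore arise in part by construction and do not show whether spironolactone blocked these genes. Of these genes Irak1 alone lay above the 75th percentile of signal, and its next brightest probe set differed by -0.08. Of all 123 genes past 2-fold, 95.1% lay below the 75th percentile, where 37.3% of the entered genes lie.

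**Figure D2:**
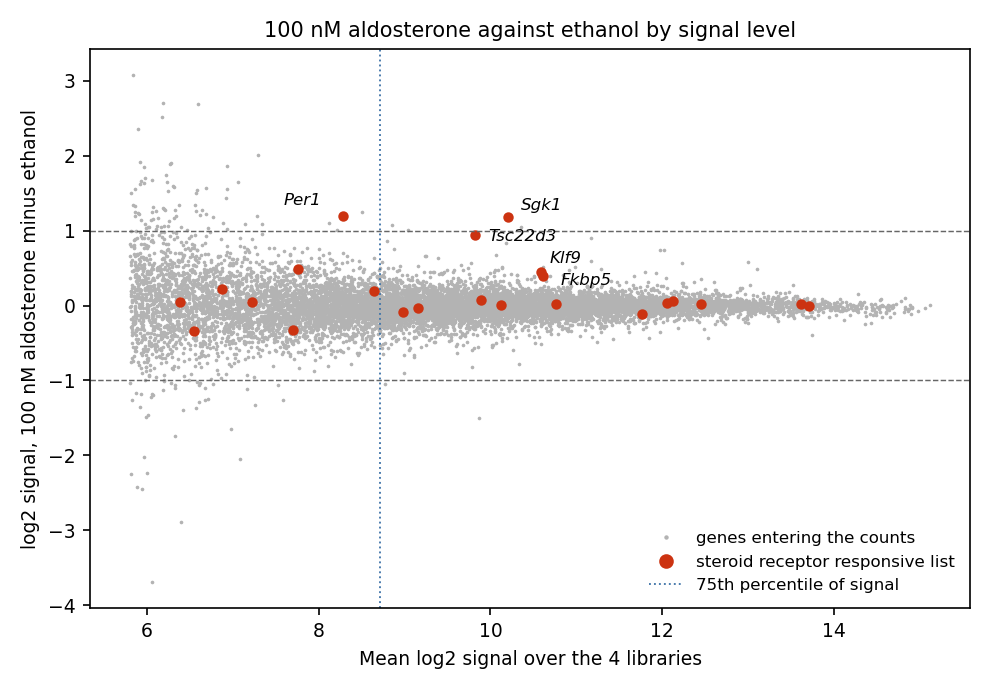
The log2 difference of each gene for 100 nM aldosterone against ethanol (y axis) is plotted against its mean log2 signal over the 4 libraries (x axis), with the steroid receptor responsive list in red, 2-fold as dashed lines and the 75th percentile of signal as a dotted line. Points spread more widely at low signal, and 95.1% of the genes past 2-fold lie below the 75th percentile.

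Above the 75th percentile 4 genes were at least 2-fold higher (Sgk1, Ski, Pan3 and Ldlrad3) and 2 lower (Irak1 and Ppp1r37). Ski, a repressor of TGF-beta signalling, was higher by 1.07 and the deadenylase subunit Pan3 by 1.05, though their next brightest probe sets differed by 0.10 and -0.19. Also higher were Mrpl33 by 0.91, the mitochondrial carnitine palmitoyltransferase Cpt2 by 0.86, Tatdn1 by 0.83 and the kinase anchor Akap12 by 0.74. The lowest after Irak1 were Ppp1r37 (-1.05), Pop1 (-0.90), Kctd7 (-0.82), the kinetochore component Nuf2 (-0.77), Rbmx (-0.69) and Taf15 (-0.66). The next brightest probe sets differed by 0.58 for Tatdn1, -0.03 for Kctd7, -0.31 for Rbmx and -0.10 for Taf15.

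The comparison of 1 nM aldosterone with ethanol asks what the lower dose does. Fkbp5 was higher by 0.52, with a signal of 1880 against 1315, and Rasl12 by 0.50. Sgk1 was higher by 0.22 (935 against 801) and Tns1 by 0.23, but the other Tns1 probe sets differed by -0.23 and -0.24. Per1 and Tsc22d3 differed by -0.04 and -0.02. The other Tsc22d3 probe sets above the filter differed by -0.04 and 0.58. Edn1, which encodes endothelin, was higher by 0.79 and Scnn1a by 0.62, both from signals near the filter.

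The steroid list's median was -0.02 (percentile 41.3), with 0 members past 1.5-fold in either direction. At their signal level 1 member (Fkbp5) lay among the highest 1% and 1 (Ddit4) among the lowest 1%. A second probe set of Fkbp5 was higher by 0.07. For 100 nM against 1 nM it differed by 0.65, and the probe set used by -0.12, so the order of the doses depends on the probe set. The nephron list lay at 0.07 (percentile 90.9) and the 5 recalled genes at 0.23 (percentile 99.4). That 0.23 is the value of the Tns1 probe set used, which the other Tns1 probe sets did not share. The lipid and insulin list was lower, at -0.10 (percentile 0.56), with Foxo3 at -0.58, and so was hypoxia and glycolysis, at -0.07 (percentile 2.29). The first moved to the 14.5th percentile with the median over probe sets, and the second to the 12.7th after quantile normalization. Growth factor and TGF-beta genes lay at 0.07 (percentile 97.0), with Spry2 at -0.66, and immediate early genes at -0.06 (percentile 9.54), with Klf6 higher by 0.52. In the S phase list E2f1 differed by -0.61, and in the xenobiotic list Gsta4 by -0.66.

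By size, 72 genes were at least 2-fold higher and 39 lower. With signals under the filter raised to it the counts were 36 and 22. Of the genes named by the rule, the adrenaline-forming enzyme Pnmt (signal 52.4 to 224) and Golga7b (21.1 to 224) were at least 4-fold higher and the ATP-gated channel P2rx7 at least 2.01-fold. Hrct1, Snx29, Serpinf2, Tbxa2r and the brush border myosin Myo7b stayed under 2-fold on that bound. The phosphatase Dusp8 was 2.53-fold lower (signal 102 against 258), and Tmc8 was lower by at least 3.02-fold, Cysrt1 by 2.96-fold and Vmn1r44 by 2.07-fold. Hps6, Bves, the polycomb component Pcgf2 and Rundc3a stayed under 2-fold on that bound. As deposited, at all 8 higher genes the ethanol library was 2-fold below all 3 others, and at 4 of the 8 lower genes the 1 nM library was. None of these genes lay above the 75th percentile of signal. Above it the highest were Cpt2 by 1.23, Tatdn1 by 1.14, Ldlrad3 by 1.06 and Tcl1b3 by 0.98. The lowest were Cdkn2a, which encodes the cell cycle inhibitors p16 and p19ARF (-1.14), Pld2 (-0.99), Kctd7 (-0.92), the centromere protein Cenpb (-0.90) and Marf1 (-0.88). The next brightest probe set of Kctd7 did not differ (0.00), and those of Tatdn1, Pld2 and Marf1 differed by 0.37, -0.21 and -0.35.

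Between the doses, the steroid list was higher with 100 nM than with 1 nM aldosterone, with a median of 0.11 (percentile 99.8), and 5 members (Sgk1, Tsc22d3, Per1, Klf9 and Ddit4) lay among the highest 1%, as many as in 0 of 10000 random lists. Without the 3 recalled genes the median was 0.09 (percentile 99.2). The nephron list did not follow: its median between the doses was -0.03 (percentile 23.8), with Sgk1, Tsc22d3 and Per1 among the highest 1% and Plaur among the lowest. Growth factor and TGF-beta genes lay at -0.16 (percentile 0) between the doses. Both doses were set against the same ethanol library. Their differences from it correlated across genes at r = 0.54 (rho = 0.49), where simulated unchanged libraries with the noise of the least spread pair, sharing an ethanol library, gave a mean of 0.50 and a highest of 0.55. The covariance was 0.0407, against a simulated mean of 0.0343 and a highest simulated value of 0.0387, which leaves 0.00644 above the mean. At both doses 39 genes were 2-fold higher, where the simulation gave 15.8 and independent lists 0.534, and 2 were 2-fold lower, where they gave 10.8 and 0.145. Of the 39 genes, 17 were also 2-fold higher with spironolactone. The simulated counts and covariance follow in part from the noise chosen, and part of any excess over them may come from the shared ethanol library, so no shared effect is read from them.

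The comparison of spironolactone with 100 nM aldosterone alone asks which differences the MR antagonist removes. Sgk1 was lower with spironolactone, with a signal of 1424 against 1810 (a log2 difference of -0.35), and was higher than in ethanol by 0.83. Per1 differed by -0.59 and Tsc22d3 by -0.46 from aldosterone alone, and they stood 0.60 and 0.48 above ethanol. Tns1 differed by -0.49, Rasl12 by -0.34 and Fkbp5 by -0.29, and they stood 0.22, 0.33 and 0.11 above ethanol. The other Tns1 probe sets differed by -0.11 and -0.19 from aldosterone alone, and those of Tsc22d3 above the filter by -0.22 and -0.09. Tgm2, a steroid-responsive transglutaminase, differed by -0.80, while the median over its 5 probe sets at or above the filter was -0.45.

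The steroid list's median was -0.07 (percentile 3.17), with 2 members (Per1 and Tgm2) lower by 1.5-fold and 0 higher; without Sgk1, Tsc22d3 and Fkbp5 the median was -0.01. Among the lowest 1% at their signal level were 4 members (Sgk1, Tsc22d3, Ddit4 and Tgm2), as many as in 1 of 10000 random lists; without the 3 recalled genes 2 remained (Ddit4 and Tgm2), as many as in 231. The nephron list lay at -0.17 (percentile 0.325), which moved to the 19.2th percentile with the median over probe sets, and the 5 recalled genes at -0.35 (percentile 0.05). Without the 3 recalled genes the nephron list lay at -0.02 (percentile 38.3), with 0 members in either tail. This comparison shares its 100 nM library with the comparison against ethanol, so opposite differences arise in part by construction.

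Hypoxia and glycolysis genes were lower with spironolactone than with aldosterone alone: the median over 20 members was -0.13, the 0th percentile. Ankrd37, a target of hypoxia-inducible factor, differed by -0.89, the mitophagy receptor Bnip3 by -0.59 and the pyruvate dehydrogenase kinase Pdk1 by -0.53. Against ethanol the median was -0.15 (percentile 0), with Pdk1 at -0.68, Ankrd37 at -0.66, Adm at -0.56 and Bnip3 at -0.50, and against 1 nM aldosterone it was -0.09 (percentile 0.02).

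Growth factor and TGF-beta genes were higher with spironolactone, at 0.12 (percentile 99.8), with Inhba higher by 0.40 and Ski lower at -0.98. Immediate early genes lay at 0.09 (percentile 99.1), with Ccn1 higher by 0.38 and Fosl1 by 0.37. Matrix genes also lay at 0.09 (percentile 98.3), which moved to the 82.5th percentile with the median over probe sets. The circadian list lay at -0.17 (percentile 0.53) but at 0.12 under the 75th percentile filter. In the lipid and insulin list Irs1 was higher by 0.65 and Acaca by 0.44, and 4 members lay among the highest 1%, as many as in 0 of 10000 random lists. The same 4 genes (Irs1, Fasn, Acaca and Foxo3) were among the lowest 1% for 100 nM against ethanol. Both comparisons share the 100 nM library, so this is no second result. Spironolactone against ethanol had 0 members in either tail. NF-kB and cytokine genes lay at 0.07 (percentile 94.5), with Ccl20 higher by 0.69, the prostaglandin synthase Ptgs2 by 0.52 and Ccl2 by 0.45; against ethanol their median was 0.11 (percentile 98.5). Distal ion transport lay at -0.10 (percentile 3.47), with the kinase Wnk4 at -0.39, while Wnk1 lay among the highest 1% at its signal level. Interferon genes lay at -0.10 (percentile 4.78), with Stat2 at -0.67.

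By size, 42 genes were at least 2-fold higher with spironolactone than with aldosterone alone and 60 lower. With signals under the filter raised to it the counts were 20 and 28. Of the genes named by the rule, Dhx38 was at least 3.82-fold higher, Fcgr2b 3.31-fold, Klf14 2.68-fold, Muc20 2.27-fold, Plxna4 2.17-fold and the desmosomal plakophilin Pkp1 2.05-fold. Fam131c, Mir142, Hes7, Chst15, Carns1 and Chst12 stayed under 2-fold on that bound. Wdr70 was 3.99-fold lower (signal 368 against 1469), Dyrk1b 2.96-fold and Cdkn2a 2.79-fold. Crispld2 was lower by at least 3.00-fold, the morphogen Bmp7 by 2.98-fold, the Wnt feedback gene Axin2 by 2.83-fold, Rasd2 by 2.58-fold and Cbfa2t3 by 2.03-fold. The mitochondrial alanyl-tRNA synthetase Aars2, Thsd7b, Grip2 and Galnt16 stayed under 2-fold on that bound. As deposited, at 10 of the 12 higher genes the 100 nM library was 2-fold below all 3 others, and at 9 of the 12 lower genes the spironolactone library was. Of these genes Wdr70 and Cdkn2a lay above the 75th percentile of signal; the next brightest probe set of Wdr70 differed by 0.09.

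Above the 75th percentile the highest with spironolactone were Irak1 by 1.31, Ppp1r37 (2.01-fold), Nfic by 0.83, Trmt61a by 0.82, Pop1 by 0.81, Tmem158 by 0.79 and Nuf2 by 0.79. The lowest after Wdr70 and Cdkn2a were Ski (-0.98), Cenpb (-0.97), Pan3 (-0.89), Marf1 (-0.83), the histone chaperone Hira (-0.83), Ap1b1 (-0.83), Ces5a (-0.81) and the iron exporter Slc40a1 (-0.74). The next brightest probe sets differed by -0.05 for Irak1, 0.47 for Tmem158, -0.01 for Ski, 0.05 for Hira and -0.17 for Slc40a1. Over the 3 probe sets of each at or above the filter, the median difference had the other sign for Marf1 (0.20) and Pan3 (0.22) in this comparison. Against ethanol, 100 nM aldosterone with spironolactone gave 46 genes at least 2-fold higher and 50 lower. The steroid list lay at 0.03 (percentile 88.3), with 3 members (Sgk1, Tsc22d3 and Per1) among the highest 1% and 1 (Ddit4) among the lowest. Without the 3 recalled genes the list lay at 0.01 (percentile 69.5), with Per1 alone among the highest 1%. Matrix genes lay at 0.16 against ethanol (percentile 99.95).

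A gene that MR induces already at 1 nM, and that spironolactone blocks in full, would be higher in both aldosterone-alone libraries than in both others. By at least 1.5-fold, 28 genes were higher there and 11 lower. With signals under the filter raised to it the counts were 19 and 9. Genes induced only at 100 nM, or blocked in part, are missed by this parting. Per1 differed by -0.04 from ethanol with 1 nM, and Sgk1 stood 0.83 above ethanol with spironolactone, so neither counted. Named by the rule above were Bmp7 (gap at least 2.30-fold), Thsd7b (at least 1.54-fold), Sncb (2.14-fold), Lce3b (2.07-fold), Cbfa2t3 (at least 2.00-fold), Platr22, Lce1b, the chemokine receptor Cxcr3, Clstn3, the T cell kinase Zap70, Sprr2k and Zscan10. Below were Vmn1r44, Cysrt1, the endothelin Edn3, Zfp689, Nectin1, Tmem200c, Nkx2-6 and Adamts6. Of these Lce1b, Zfp689 and Nectin1 fell out once signals were raised to the filter, with bounds of 1.46-fold, 1.35-fold and 1.39-fold. Above the 75th percentile of signal the counts were 0 and 0. Parting both libraries given 100 nM aldosterone from ethanol and 1 nM gave 19 higher and 9 lower, among them Sgk1 by a gap of 0.61 and Per1 by 0.60. Parting 1 nM and spironolactone from ethanol and 100 nM gave 12 higher and 15 lower, among them Cdkn2a. Counts for these other partings are by signals as deposited, not raised to the filter. Above the 75th percentile they were 1 and 0 for the parting of both 100 nM libraries, and 0 and 5 for that of 1 nM and spironolactone. Across genes, the difference of 1 nM aldosterone from ethanol and that of 100 nM aldosterone from spironolactone, which share no library, correlated at r = 0.03 (rho = 0.01). For the other such pair, 100 nM aldosterone from ethanol and 1 nM from spironolactone, given after seeing the data, r was 0.08 (rho = 0.11). The pairs formed the same way for 1 nM and spironolactone against ethanol and 100 nM gave r = -0.03 and 0.05 (rho = -0.01 and 0.10). Those for both 100 nM libraries against ethanol and 1 nM gave -0.08 and -0.05 (rho = -0.11 and -0.10). These are no separate reference: turning a difference around only flips the sign. By construction, -0.03 and -0.08 repeat the 0.03 and 0.08 of the parting by aldosterone alone, and -0.05 repeats 0.05.

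All 6 pairs of libraries gave similar numbers of genes past 2-fold: 123 for 100 nM against ethanol, 111 for 1 nM against ethanol, 105 for spironolactone against 1 nM, 102 for spironolactone against 100 nM, 96 for spironolactone against ethanol and 92 for 100 nM against 1 nM. Above the 75th percentile of signal the totals ran from 2 to 6, and with a 1.5-fold rule added after seeing the data from 17 to 44.

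**Figure D3:**
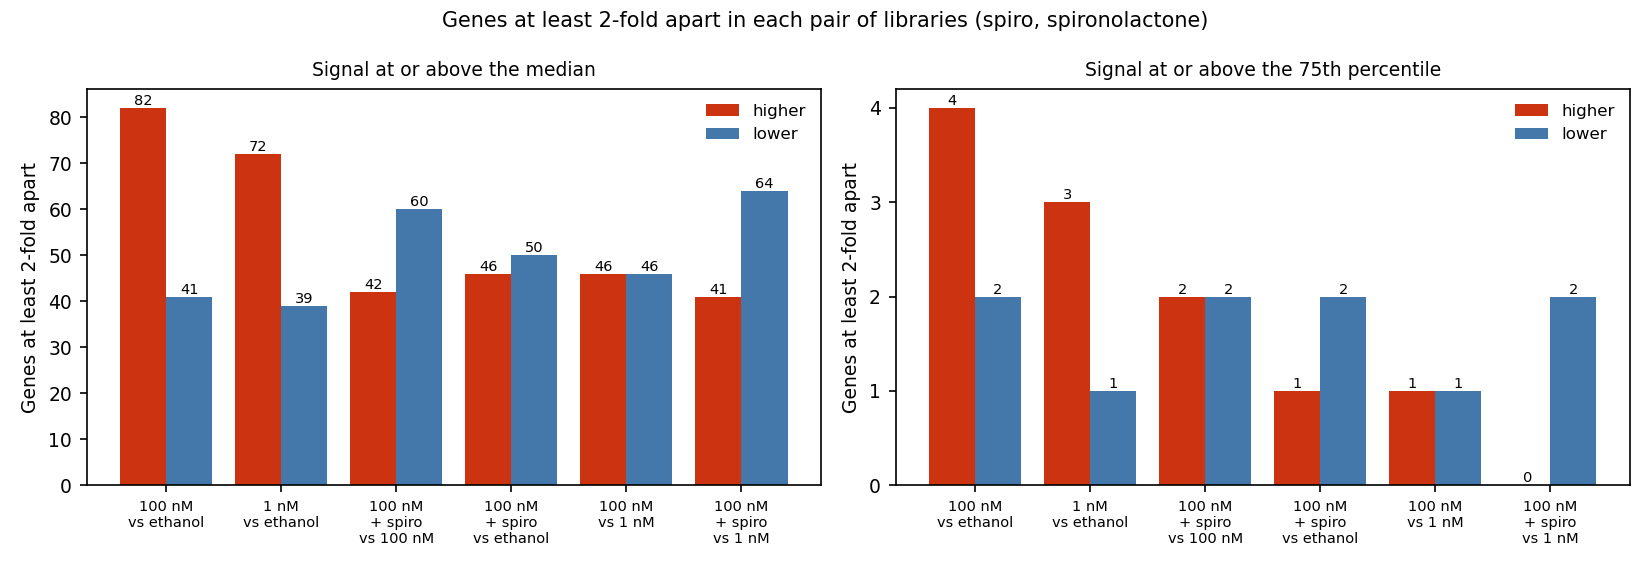
Bars give the number of genes (y axis) at least 2-fold higher (red) and lower (blue) in each of the 6 pairs of libraries (x axis), for all genes that entered (left) and for those above the 75th percentile of signal (right). Totals run from 92 to 123 over all entered genes and from 2 to 6 above the 75th percentile.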

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

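All tests weighed here were chosen only after the result was seen, except the repeats after quantile normalization.

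A pair of probe sets listed for both Rps6, a ribosomal protein gene, and its relative Rps6-ps4 was left out of the comparisons because it names several genes, and stood out as signal outside the main measurement. Their signals were 2411 and 1099 in ethanol, the lowest library for both, 6486 and 2316 with 1 nM aldosterone (2.69-fold and 2.11-fold higher), 3750 and 1903 with 100 nM, and 4020 and 1286 with spironolactone. In all, 10092 probe sets carried no single gene name, of which 860 lay above the 75th percentile of signal. The ribosomal protein list, which holds Rps6 through another probe set, differed by a median of -0.06 in that comparison, and Rps6 itself by -0.08.

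Every pair of libraries held between 92 and 123 genes past 2-fold, whichever treatments were compared. If a difference in scaling between the arrays had made these calls, quantile normalization would have removed many. It left 119 genes past 2-fold for 100 nM aldosterone against ethanol, where there were 123. The arrays already shared a trimmed mean of 499.8, so this bears only on scaling differences that remained. Noise of dim probe sets may account for many of them, but the share is not settled. Where the gene had another probe set that entered, 16.7% (2 of 12) showed at least a 1.5-fold difference in the same direction there. The sign was the same for 7 of the 12. These 12 of the 123 genes include the brighter Irak1, Ski and Pan3, so they say little of the dim genes. A probe set can also differ from another of its gene because it reads another transcript end, so a share of true differences among the dim genes stays open. No replicate exists to part the remaining true differences from noise.

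The libraries given ethanol and 100 nM aldosterone parted from those given 1 nM aldosterone and spironolactone in how differences ran with gene span, which no treatment in the design predicts. Above the 75th percentile of signal, the rank correlation with span of the difference, taken as 1 nM or spironolactone minus ethanol or 100 nM, over 6929 of 6937 genes, was at least 0.108 in the 4 pairs that cross this parting, so longer genes stood higher on the 1 nM and spironolactone side, and was -0.00500 and -0.0169 in the others. A constant scaling factor adds the same amount to every log2 difference, so this rank correlation cannot depend on it. Only scaling that varies with signal is argued against, since the lowest crossing value after quantile normalization was 0.111. RNA or labelling that differed between the arrays could produce such a trend, but with 1 library per group it cannot be told apart from a treatment effect, and no array date is used here. The 5' probe set of 18S ribosomal RNA parted the same way, with signals of 9346 and 10368 against 6897 and 7560, and so did Cdkn2a, with 6210 and 7295 against 2812 and 2616.

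Some steroid receptor responsive genes were high with 100 nM aldosterone, with 5 of 23 members among the highest 1% at their signal level, while the list's median of 0.04 lay at the 92.6th percentile. Without Sgk1, Tsc22d3 and Fkbp5, recalled from the study's publication, 2 members (Per1 and Klf9) remain there, as many as in 203 of 10000 random lists, so noise usual at their signal level stays open. The array difference along gene span is argued against for 100 nM aldosterone against ethanol alone, since the rank correlation with span was -0.00500 there. It was -0.135 for 100 nM against 1 nM and 0.108 for spironolactone against 100 nM. Against ethanol it was 0.127 for 1 nM and 0.118 for spironolactone. For the steroid list's differences in those comparisons, Sgk1 included, the array difference stays open. Endogenous glucocorticoid receptor in place of the transfected receptor stays open: Nr3c1 had a signal of 1959 in ethanol, no library without the human receptor is analysed here, and Sgk1 was still higher by 0.83 after spironolactone. An effect of aldosterone through MR is the biological hypothesis that the design names, and it was not tested apart from the glucocorticoid receptor.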

How the results depend on the processing

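The tests without the recalled genes, with signals raised to the filter, over probe sets at or above the filter, and on the other pairs of differences that share no library were chosen after the result was seen. The others were fixed in advance. Counts below are genes higher and lower, in the order 100 nM aldosterone against ethanol, 1 nM against ethanol, spironolactone against 100 nM, spironolactone against ethanol, 100 nM against 1 nM, and spironolactone against 1 nM. The cause of a move was not tested except where a filter or size rule changes by construction how many genes can count.

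The 75th percentile filter gave 4 and 2, 3 and 1, 2 and 2, 1 and 2, 1 and 1, and 0 and 2, with 0 and 0 for the parting by aldosterone alone and r = -0.041 between the differences that share no library (0.14 for the other such pair). Under that filter the pairs for 1 nM and spironolactone against ethanol and 100 nM gave r = 0.041 and 0.18. Those for both 100 nM libraries against ethanol and 1 nM gave -0.14 and -0.18. By construction these values repeat each other with the sign turned, so they are no separate reference. No filter gave 1655 and 1426, 1707 and 1361, 1380 and 1742, 1486 and 1597, 1422 and 1554, and 1266 and 1748, with 543 and 367 for the parting, r = 0.0093 for the differences that share no library and r = 0.52 between the doses. The 1.5-fold rule gave 264 and 190, 289 and 229, 202 and 277, 240 and 225, 226 and 217, and 194 and 294, and a 2-fold rule gave 6 and 0 for the parting. The pseudocount gave 54 and 26, 45 and 16, then 37 lower and 27 lower in the next pairs, 24 and 30, and 21 and 34, with 14 higher for the parting and r = 0.53 between the doses. The median over probe sets gave 106 lower and 86 lower against ethanol, then 95 and 126, 74 and 105, 72 and 89, and 63 and 110, with 23 lower for the parting. Raising signals under the filter to it gave 47 and 22, 36 and 22, 20 and 28, 20 and 23, 27 and 23, and 18 and 33. Quantile normalization moved none of these counts by over 1.5 times. Median centring moved the steroid list with 1 nM aldosterone to -0.083, and without Sgk1, Tsc22d3 and Fkbp5 the list with spironolactone against 100 nM lay at -0.0092.

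With the median over probe sets 18 differences took the other sign. That median is taken in each library and can set a dim probe set of a gene against another, as for Bmp7, so it does not by itself show a reversal; over probe sets at or above the filter the sign turned for 3 (Cd99l2, Marf1 and Pan3). For spironolactone against 100 nM these were Abl1 (-0.48), Axin2 (0.038), Bmp7 (1.68), Esr1 (0.35), Fcgr2b (-0.21), Marf1 (0.20), Nfic (-0.44), Pan3 (0.17), Tgm2 (0.0095) and Thsd7b (0.80). For 1 nM against ethanol they were Atp13a2 (-0.24), Cd99l2 (0.14), Cenpb (0.11), Pithd1 (0.014) and Slc5a2 (-0.17), and for 100 nM against ethanol Flt1 (0.10), Klf6 (-0.018) and Lsm12 (-0.050). The circadian list with spironolactone reversed to 0.12 under the 75th percentile filter, and the fibroblast list with 1 nM to -0.012 with no filter and -0.074 under the 75th percentile filter. Of the other values, 1825 moved by less than the spread of genes of like signal, or of random lists, and 279 by more, without reversing. Lists with no member above the 75th percentile got no value there. Low signal limits the comparisons: at least 95.1% of the 2-fold differences in each pair lay in the dimmer 37.3% of genes.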

Other observations

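The counts of members among the highest or lowest 1% at their signal level, and that of genes at which 1 library stood apart, were chosen after the results were seen; the list medians were fixed in advance.

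Markers of other kidney and stromal cell types were mostly dim in these cells, and few of them entered. For 100 nM aldosterone against ethanol, the proximal tubule markers had a median difference of 0.11 over 8 members (percentile 80.9), with Slc22a12 at least 1.76-fold higher when its signal of 27.3 in ethanol is raised to the filter. The collecting duct and intercalated markers had 0.26 over 2 members (percentile 89.4), with the transcription factor Tfcp2l1 higher by 0.45. Fibroblast markers had 0.11 over 5 members (percentile 90.8), endothelial markers -0.13 over 6 (percentile 18.3) and leukocyte markers -0.05 over 6 (percentile 26.1). With 1 nM aldosterone the fibroblast markers lay at 0.23 (percentile 98.1), but at -0.01 with no filter.

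Growth and stress programs that the text above leaves aside differed little with 100 nM aldosterone against ethanol. The S phase list lay at the 63.0th percentile and G2 and mitosis at the 87.9th, with medians of 0.00 and 0.02, although the kinetochore gene Nuf2 differed by -0.77. The unfolded protein and amino acid stress list had a median of 0.00 (percentile 58.2), with the stress-induced Sesn2 at -0.44. Heat shock genes had -0.01 (percentile 32.0), the xenobiotic and oxidative list -0.03 (percentile 28.7), with the retinal dehydrogenase Aldh1a1 at -0.91. Ribosomal proteins had -0.01 (percentile 41.3) and housekeeping genes -0.03 (percentile 18.2).

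The spironolactone library held the hypoxia and glycolysis list low against each of the other 3 libraries, with percentiles of 0, 0 and 0.02, and 4 of its 20 members (Pdk1, Bnip3, Ankrd37 and Pgk1) lay among the lowest 1% at their signal level against ethanol, as many as in 0 of 10000 random lists. The NF-kB and cytokine list was higher with spironolactone than with 1 nM aldosterone by a median of 0.22 (percentile 100), with Ccl2 and Cxcl1 among the highest 1%. The G2 and mitosis list was lower in that comparison, at -0.06 (percentile 0.13). No explanation was tested for these differences. The spironolactone library also received 100 nM aldosterone, so against 1 nM aldosterone the dose differs as well. Over all lists and pairs, 14 of 162 combinations held at least 3 members in one tail. Of these 10 came from the steroid, nephron and recalled lists, which share members, and 4 from the lipid, hypoxia and immediate early lists. The 2 from the lipid list hold the same genes, in comparisons that share the 100 nM library.

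Library by library, 17 genes were at least 2-fold below all the others in ethanol, 6 with 1 nM aldosterone, 17 with 100 nM and 14 with spironolactone, and 0, 3, 2 and 0 were 2-fold above. Above the 75th percentile of signal these counts were 0 or 1; the ones below all others were Irak1 with 100 nM aldosterone and Wdr70 with spironolactone. The ratio of 3' to 5' signal was between 0.741 and 0.783 for Gapdh and between 1.26 and 1.33 for Actb.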
